A study of Mus musculus with 48 samples.

How the data were processed

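RNA was measured in 6 cell populations sorted by flow cytometry from mouse ear skin: dermal monocytes, monocyte-derived dendritic cells (moDC), dermal macrophages with low or high surface MHC class II (MHCIIlow and MHCIIhi), dermal CD11b dendritic cells (CD11b DC) and epidermal Langerhans cells. Per the labels, mice of 8 to 11 weeks received 5% imiquimod cream on the ears in a 14-day course, and cells were taken from untreated skin or at day 5 or day 11 of treatment. The 48 arrays (Affymetrix mouse gene arrays, hybridised after 2 rounds of amplification from 1 to 20 ng of RNA) form 16 groups of 3. Monocytes were profiled untreated and at day 5, MHCIIhi macrophages untreated and at day 11, and the other 4 populations in all 3 conditions. The labels describe digestion with dispase at either of a pair of temperatures, and which sample received which is not given. They also do not say whether the 3 samples of a group come from separate mice, so p-values measure the spread between these samples.

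The deposited values are log2 expression values that the authors had already normalised together by RMA (background correction, quantile normalisation and summary per probe set). The submitters' processing notes credit RMA, the oligo package and limma, with versions not given. The deposited series table, the authors' full table and a shorter table of 5958 probe sets held the same values (largest difference 0). The full table was used without further normalisation. The number of arrays limits the precision of every value.

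Of 35556 probe sets, 21789 carried 1 gene symbol, 1621 carried several and 12146 carried none. Symbols were checked against RefSeq by gene identifier for 21698 probe sets, and 0 changed. A probe set was kept when its log2 value exceeded the 40th percentile of all values (3.77) on at least 3 arrays, which kept 17017 probe sets with 1 symbol. The probe set with the highest mean represented each gene, leaving 15591 genes, of which 810 had more than 1 kept probe set. Probe sets without a single symbol were tested apart.

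One limma model (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with a mean for each of the 16 groups was fitted to all 48 arrays. It gave 20 contrasts: imiquimod day 5 and day 11 against untreated in each population, day 11 against day 5, 4 pairs of untreated populations, and the Langerhans cell response minus the mean response of the 4 dermal populations at each day. Tests were two-sided, adjusted by Benjamini-Hochberg over all genes within a contrast, and a gene was called at an adjusted p under 0.05. A stricter count also asked for a log2 change of at least 1.

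Gene lists, 27 in number, were fixed before the data were examined, as were the contrasts, filter, tests, naming rule and all alternatives but 1. They cover S phase, G2 and M phase, interferon-stimulated genes, inflammatory mediators, chemokines, regulatory mediators, the NF-kB pathway, endosomal Toll-like receptor sensing, MHC class II and antigen presentation, dendritic cell maturation, Langerhans cell identity, macrophage core, alternative activation, monocyte signature, conventional DC core, glycolysis, oxidative phosphorylation, cholesterol synthesis, lysosome and lipid handling, and the early stress response to dissociation. Further lists hold markers of keratinocytes, fibroblasts, T cells, B cells, neutrophils, mast cells, and endothelial cells with melanocytes. Each was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted within each family of contrasts. Each was also tested, far more strictly, with its correlation estimated from the data. Of the calls, 24 of 64 held with an estimated correlation at day 5, 7 of 52 at day 11, 14 of 52 between the days, 28 of 59 between untreated populations and 8 of 33 for the response differences.

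Genes named in the text were chosen by rule. They are the genes past the test with the largest changes whose values did not overlap between the groups (8 rises and 8 falls for Langerhans cells under imiquimod, 5 and 5 for other populations, 3 and 3 for all other contrasts), up to 4 members of each called list, and a fixed panel of cytokines, receptors and proliferation markers. Chance alone gives non-overlapping values in 10% of comparisons of 3 arrays with 3. Genes shared by all populations and the keratinocyte genes weighed in closing are also named.

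On simulated data the fit called 16 of 67 genes (23.9%) at a true log2 change of 0.5 and 42 of 67 (62.7%) at 1. At 2 it called 66 of 66, with 8 false calls in all (6.06%). With no true change it called 0. Of 200 simulated lists camera called only the shifted one, but genes were independent, so calls due to correlation were untested.

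Alternatives were quantile normalisation or median-centring of the arrays, no filter or a stricter one (60th percentile), the mean of a gene's probe sets, fitting only the groups compared, eBayes with trend and robust options, array weights, replicate numbers as a block, the 2-fold threshold, and leaving out each array in turn. Leaving out both arrays said below to stand apart was added after the data were seen.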

Results

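The 48 arrays (16 groups of 3) covered 6 skin mononuclear phagocyte populations, untreated or under imiquimod, a Toll-like receptor 7 agonist inducing psoriasis-like inflammation. The median log2 value per array ran from 4.10 to 4.37, and 12677 to 14010 of 15591 genes lay above the filter threshold on each array. Arrays of the same group correlated at 0.926 to 0.988, and 43 of 48 arrays matched another array of their own group best. Untreated monocyte replicates 1 and 2 matched untreated moDC best. The first 4 principal components held 26.3%, 15.9%, 11.9% and 7.65% of the variance. Replicate 2 of untreated monocytes (mean correlation with its group 0.932) and of CD11b DC at day 11 (0.945) stood farthest apart.

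Below, a change is a log2 difference between group means ± SE from the limma fit, with n = 3 arrays in each group. "Rose" and "fell" mark genes past an adjusted p of 0.05, and the genes with the largest changes had all 3 arrays of one group outside the range of the other. The letter after BMN_ in sample titles differs between untreated, day 5 and day 11 samples of the dermal populations, between day 11 and earlier Langerhans cells, and between untreated Langerhans cells and CD11b DC. A batch that followed these letters cannot be told apart from treatment, day or population there. Untreated and day 5 Langerhans cells share this letter, but their pairs (FS, FJ) differ and no meaning is given.

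**Figure D1:**
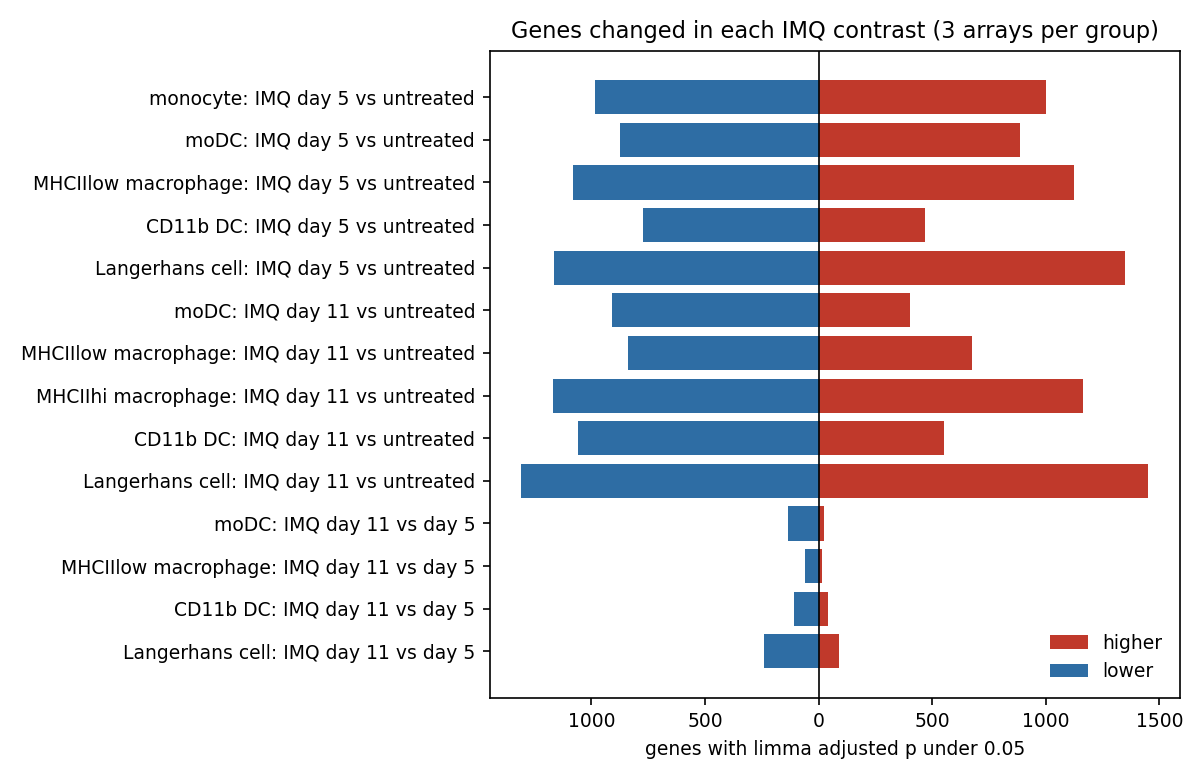
Number of genes past an adjusted p of 0.05 (limma) in each comparison of imiquimod with untreated cells and of day 11 with day 5. Higher genes and lower genes are separate bars on a linear axis from 0, n = 3 arrays per group. Langerhans cells had 2514 genes at day 5 and 2762 at day 11.

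Untreated moDC, compared with untreated dermal monocytes to show what differs between these cells before treatment, expressed more Retnla, a secreted product of alternatively activated macrophages (+6.86 ± 0.78), the lectin Mgl2 (+6.18 ± 0.38) and the CCR4 ligand Ccl17 (+5.46 ± 0.40). Among genes of MHC class II and antigen presentation, 7 of 19 measured genes were higher, 0 were lower and 12 were not past the test (8 and 1 adjusted over the list alone). H2-Eb1 stood at +3.76 ± 0.15 and H2-Ab1 at +2.19 ± 0.16 (list adjusted p = 7.27e-12, and 9.58e-05 with an estimated correlation). In the conventional DC core list, 11 of 35 measured genes were higher, 1 was lower and 23 were not past the test (15 and 2 adjusted over the list alone). These included Cd209a (+3.70 ± 0.33) and Clec10a (+3.67 ± 0.46), at a list adjusted p = 1.46e-15, and 0.00025 with an estimated correlation. Of the G2 and M phase genes, 11 of 35 genes were higher, 0 were lower and 24 were not past the test (15 and 0 adjusted over the list alone). Top2a stood at +2.29 ± 0.30 and Mki67, a marker of cycling cells, at +1.65 ± 0.30 (list adjusted p = 2.68e-13, and 0.0146 with an estimated correlation). Of the alternative activation genes, 8 of 26 genes were higher, 1 was lower and 17 were not past the test (12 and 1 adjusted over the list alone). These included Cd163 (+4.25 ± 0.35), at a list adjusted p = 6.87e-14, and 0.00253 with an estimated correlation. The monocyte signature ran the other way: 0 of 19 genes were higher, 9 were lower and 10 were not past the test (0 and 11 adjusted over the list alone). Ifitm6 stood at -3.32 ± 0.57 and Itgal at -2.71 ± 0.28 (list adjusted p = 1.43e-12, and 0.000929 with an estimated correlation). Keratinocyte markers had a median of 0.33 with 0 of 25 past the limma test gene by gene (list adjusted p = 0.031, and 0.614 with an estimated correlation). In all, 336 genes were higher and 198 lower (534), and 351 of them changed at least 2-fold. Fitting only these groups left 76 genes, array weights left 258, and omitting both arrays that stood apart raised the count to 825.

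MHCIIhi macrophages, compared with MHCIIlow macrophages in untreated skin, had 86 genes higher and 54 lower. Highest were Ccl17 (+5.98 ± 0.40), the related chemokine Ccl22 (+3.88 ± 0.45) and H2-Eb1 (+3.56 ± 0.15), while Cmah, an enzyme of sialic acid modification, was lower (-2.17 ± 0.18). Of the antigen presentation genes, 7 of 19 genes were higher, 0 were lower and 12 were not past the test (8 and 0 adjusted over the list alone). These included H2-Ab1 (+2.50 ± 0.16), at a list adjusted p = 3.79e-23, and 2.24e-07 with an estimated correlation. Of the dendritic cell maturation genes, 6 of 27 genes were higher, 0 were lower and 21 were not past the test (9 and 0 adjusted over the list alone). These included the lymph node homing receptor Ccr7 (+2.29 ± 0.32), at a list adjusted p = 4.46e-11, and 0.00294 with an estimated correlation. Mast cell markers tended the other way at the level of the list: 0 of 8 genes were higher, 1 was lower and 7 were not past the test (0 and 6 adjusted over the list alone), median -0.88 (adjusted p = 1.74e-07, and 0.04 with an estimated correlation). T cell markers had a list median of 0.22 (adjusted p = 0.0266, and 0.247 with an estimated correlation) with 0 of 14 past the limma test over all genes and 1 adjusted over the list alone. The comparison gave 140 genes, and 19 when only these groups were fitted.

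CD11b DC, compared with untreated moDC, had lower Chil3, a chitinase-like secreted protein (-5.33 ± 0.46), lower Dpt, an extracellular matrix protein of fibroblasts (-5.34 ± 0.79), and higher Clec4g (+2.84 ± 0.35). Of the monocyte signature, 0 of 19 genes were higher, 9 were lower and 10 were not past the test (0 and 11 adjusted over the list alone). Vcan stood at -4.24 ± 0.22 and Plac8 at -4.20 ± 0.61 (list adjusted p = 3.66e-19, and 8.02e-05 with an estimated correlation). Macrophage core genes were also lower, including the Fc receptor Fcgr1 (-1.98 ± 0.33): 0 of 45 genes were higher, 9 were lower and 36 were not past the test (0 and 13 adjusted over the list alone), list adjusted p = 7.27e-12, and 0.0146 with an estimated correlation. In the conventional DC core list, 13 of 35 genes were higher, 0 were lower and 22 were not past the test (17 and 2 adjusted over the list alone). These included Jaml (+1.73 ± 0.34), at a list adjusted p = 1.82e-07, and 0.00961 with an estimated correlation. Of the lysosome and lipid handling genes, 0 of 25 genes were higher, 10 were lower and 15 were not past the test (0 and 13 adjusted over the list alone). Gpnmb stood at -3.38 ± 0.47 (list adjusted p = 8.02e-13, and 0.00606 with an estimated correlation). Fibroblast markers moved with these groups: 0 of 14 genes were higher, 10 were lower and 4 were not past the test (0 and 12 adjusted over the list alone). Lum stood at -4.29 ± 0.73 (list adjusted p = 5.87e-18, and 0.0146 with an estimated correlation). The comparison gave 300 higher and 257 lower genes, 557 in all (53.9% higher, and 66.8% with median-centred arrays). Fitting only these groups left 191 genes, and leaving out untreated CD11b DC replicate 2 left 357.

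Untreated Langerhans cells, compared with untreated CD11b DC as the dermal dendritic cells (their title letters differ), carried far more Cd207 (langerin, +5.78 ± 0.47), the adhesion molecule Epcam (+4.23 ± 0.20) and Mmp9, a matrix protease (+6.04 ± 0.24), and far less lysozyme Lyz1 (-8.28 ± 0.41), Ccl17 (-7.33 ± 0.40) and the monocyte chemokine receptor Ccr2 (-6.56 ± 0.38). Of the Langerhans cell identity genes, 13 of 22 genes were higher, 1 was lower and 8 were not past the test (13 and 1 adjusted over the list alone). Mfge8 stood at +5.44 ± 0.49 (list adjusted p = 2.02e-09, and 0.0007 with an estimated correlation). Chemokine genes were lower, such as Ccl9 (-7.40 ± 0.33): 2 of 24 genes were higher, 13 were lower and 9 were not past the test (2 and 13 adjusted over the list alone), list adjusted p = 4.02e-08, and 0.0146 with an estimated correlation. Endosomal Toll-like receptor genes were lower as well, led by the receptor chaperone Unc93b1 (-4.59 ± 0.37): 1 of 17 genes was higher, 10 were lower and 6 were not past the test (1 and 13 adjusted over the list alone), list adjusted p = 1.5e-06, and 0.00736 with an estimated correlation. Cholesterol synthesis genes were higher, with Hmgcs1 at +2.94 ± 0.29: 14 of 20 genes were higher, 0 were lower and 6 were not past the test (16 and 0 adjusted over the list alone), list adjusted p = 4.53e-09, and 0.00197 with an estimated correlation. Among G2 and M phase genes, 0 of 35 genes were higher, 19 were lower and 16 were not past the test (1 and 22 adjusted over the list alone), and Mki67 stood at -2.50 ± 0.30 (adjusted p = 7.86e-07, and 0.104 with an estimated correlation). Keratinocyte markers were higher beside all of these, with Dsc3, a desmosomal cadherin, at +4.88 ± 0.37: 21 of 25 genes were higher, 0 were lower and 4 were not past the test (21 and 0 adjusted over the list alone), median 3.51 (adjusted p = 1.92e-19, and 0.00961 with an estimated correlation). Of 3603 genes, 1751 were higher and 1852 lower, and 1995 changed at least 2-fold. Median-centring moved the higher share from 48.6% to 38.5%.

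In Langerhans cells, the subject of the series title, day 5 of imiquimod brought the alarmins S100a8 (+7.55 ± 0.77) and S100a9 (+7.03 ± 0.43), the chemokine Ccl17 (+5.91 ± 0.40), the actin-bundling protein of mature dendritic cells Fscn1 (+5.46 ± 0.49), the cysteine protease inhibitor Stfa2 (+5.34 ± 0.31) and the interferon-inducible Ifitm1 (+5.11 ± 0.49). Ccl17 stood at 4.92 ± 0.33 (SD, n = 3) untreated and 10.83 ± 0.17 at day 5. The cell division genes rose almost as a block: of the G2 and M phase list, 33 of 35 genes rose, 0 fell and 2 were not past the test (34 and 0 adjusted over the list alone). Bub1 stood at +2.96 ± 0.28, Top2a at +2.67 ± 0.30 and Plk1, a mitotic kinase, at +2.52 ± 0.37 (list adjusted p = 3.72e-32, and 0.000848 with an estimated correlation). The mean of these genes moved from 4.94 ± 0.103 (SD, n = 3) untreated to 6.66 ± 0.305, and Mki67 rose by +1.68 ± 0.30. Of the S phase genes, 13 of 30 genes rose, 0 fell and 17 were not past the test (15 and 0 adjusted over the list alone). These included the ribonucleotide reductase subunit Rrm2 (+2.01 ± 0.38), at a list adjusted p = 1.61e-06, and 0.0397 with an estimated correlation.

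Maturation genes made up another large group in Langerhans cells at day 5. The mean of the dendritic cell maturation and migration list was 5.78 untreated and 7.60 at day 5, against 7.62 in CD11b DC at day 5. For the lists of this paragraph, RNA of other populations in the Langerhans cell samples was not tested. Of the dendritic cell maturation and migration list, 18 of 27 genes rose, 1 fell and 8 were not past the test (18 and 1 adjusted over the list alone). These included Ccl22 (+4.58 ± 0.45), Tnfrsf9 (+4.20 ± 0.34) and Ccr7 (+3.19 ± 0.32), at a list adjusted p = 1.46e-14, and 0.00113 with an estimated correlation. Of the chemokines, 10 of 24 genes rose, 2 fell and 12 were not past the test (12 and 2 adjusted over the list alone). Ccl9 stood at +4.40 ± 0.33 (list adjusted p = 1.73e-08, and 0.0213 with an estimated correlation). In the monocyte signature, 12 of 19 genes rose, 1 fell and 6 were not past the test (12 and 1 adjusted over the list alone). Plac8 stood at +4.59 ± 0.61 and Ccr2 at +3.77 ± 0.38 (list adjusted p = 1.91e-06, and 0.0244 with an estimated correlation). In the conventional DC core list, 21 of 35 genes rose, 1 fell and 13 were not past the test (24 and 3 adjusted over the list alone). These included the transcription factor Irf8 (+2.58 ± 0.29), at a list adjusted p = 2.12e-11, and 0.00197 with an estimated correlation. Of the antigen presentation genes, 7 of 19 genes rose, 0 fell and 12 were not past the test (9 and 0 adjusted over the list alone). The immunoproteasome subunit Psmb8 stood at +1.88 ± 0.11 (list adjusted p = 0.000168, and 0.0243 with an estimated correlation). Interferon-stimulated genes were past the list test only at the preset correlation: 14 of 34 genes rose, 0 fell and 20 were not past the test (18 and 0 adjusted over the list alone). Irf7 stood at +2.01 ± 0.46 (list adjusted p = 3.63e-07, and 0.0596 with an estimated correlation). The cytokines Il1b (+3.77 ± 0.48) and Il23a, a subunit of the psoriasis cytokine IL-23 (+1.86 ± 0.27), rose, and so did the checkpoint ligands Cd274 (PD-L1, +2.88 ± 0.39) and Pdcd1lg2 (PD-L2, +3.43 ± 0.44). On the 3 day 5 arrays Il23a stood at 5.13, 5.01 and 6.93. Of the inflammatory mediators, 5 of 22 genes rose, 1 fell and 16 were not past the test (5 and 1 adjusted over the list alone), list adjusted p = 0.0248, and 0.303 with an estimated correlation. Of the regulatory mediators, 6 of 23 genes rose, 1 fell and 16 were not past the test (7 and 1 adjusted over the list alone), list adjusted p = 0.0393, and 0.184 with an estimated correlation. Quantile normalisation (adjusted p = 0.0771) and array weights (0.0534) each end the call of the regulatory list. Cd207 (-0.53 ± 0.47), Il10 (+0.58 ± 0.47), Il6 (+0.96 ± 0.66) and Tnf (-0.29 ± 0.46) were not past the test.

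The falls in Langerhans cells at day 5 were led by genes of keratinocytes and other epidermal cells: the keratin Krt24 (-5.40 ± 0.18), Skint9, a member of an epidermal immunoglobulin family (-4.91 ± 0.23), Slurp2 (-4.42 ± 0.41), the epidermal transcription factor Ovol1 (-4.40 ± 0.34) and the ceramidase Acer1 (-4.38 ± 0.38). Of the keratinocyte markers, 4 of 25 genes rose, 13 fell and 8 were not past the test (4 and 15 adjusted over the list alone), median -1.38 (adjusted p = 1.47e-06, and 0.197 with an estimated correlation). Members moved both ways, with Krt15 at -3.88 ± 0.56 and Sfn at -2.99 ± 0.45 but the cornified envelope gene Sprr2d at +3.70 ± 0.68. Il34, a Csf1r ligand made by keratinocytes, fell (-2.89 ± 0.24). Early stress genes tied to dissociation were lower: 0 of 26 genes rose, 6 fell and 20 were not past the test (0 and 8 adjusted over the list alone), list adjusted p = 0.00058, and 0.198 with an estimated correlation. Fibroblast markers had a list median of 0.79, including Dcn (+2.89 ± 0.56): 6 of 14 genes rose, 0 fell and 8 were not past the test (6 and 0 adjusted over the list alone), list adjusted p = 0.0165, and 0.612 with an estimated correlation. Of the neutrophil markers, 6 of 14 genes rose, 1 fell and 7 were not past the test (6 and 1 adjusted over the list alone), list adjusted p = 0.0444, and 0.162 with an estimated correlation. The comparison called 2514 genes, 1347 higher and 1167 lower, and 1349 of them changed at least 2-fold.

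**Figure D2:**
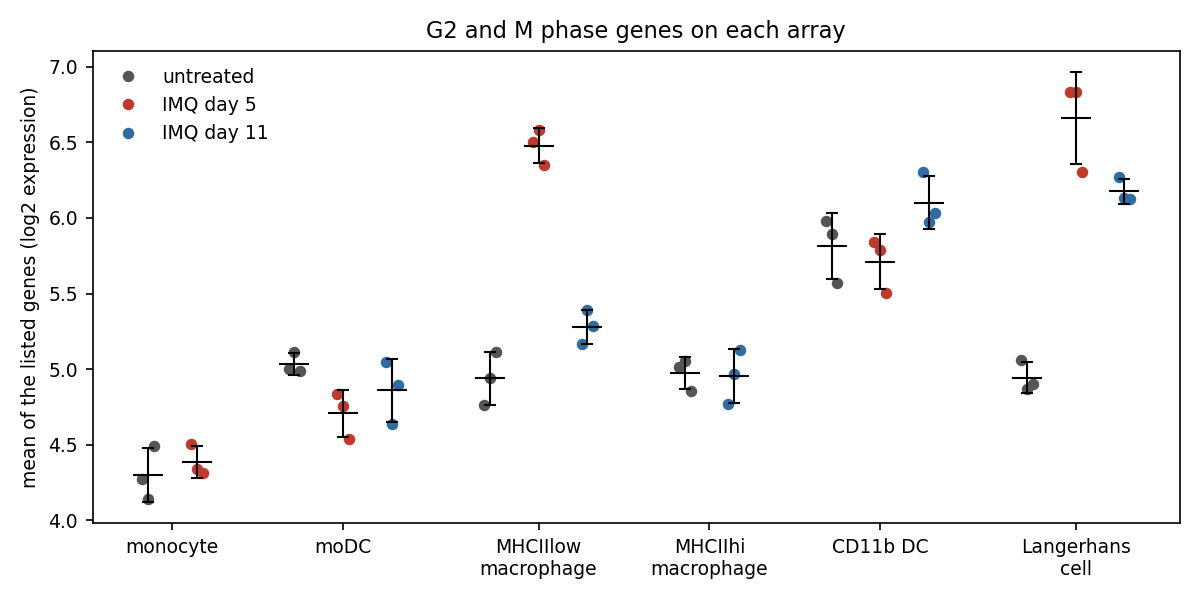
Mean log2 expression of the G2 and M phase list on each array (points), by population and condition, with bars for the group mean ± SD of 3 arrays. Langerhans cells stood at 4.94 untreated, 6.66 at day 5 and 6.18 at day 11, and MHCIIlow macrophages at 4.94, 6.48 and 5.28.

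At day 11, the later time point under continued treatment, Langerhans cells carried high S100a8 (+7.52 ± 0.77), Ccl17 (+5.28 ± 0.40, a level of 10.20 ± 0.14, SD, n = 3) and Ccl22 (+4.21 ± 0.45). The retinol carrier Rbp4 (+5.39 ± 0.27), the nucleotide receptor P2ry6 (+4.96 ± 0.25) and the adhesion receptor Adgre5 (+4.33 ± 0.22) were among the largest rises. Of the G2 and M phase genes, 29 of 35 genes rose, 0 fell and 6 were not past the test (32 and 0 adjusted over the list alone). Aurkb stood at +2.34 ± 0.34 and Ccna2 at +2.19 ± 0.44 (list adjusted p = 4.25e-17, and 0.0301 with an estimated correlation), while Mki67 itself stood at -0.21 ± 0.30 and was not past the test. Of the antigen presentation genes, 9 of 19 genes rose, 0 fell and 10 were not past the test (10 and 0 adjusted over the list alone). The peptide transporter Tap1 stood at +1.37 ± 0.18 (list adjusted p = 1.39e-05, and 0.0301 with an estimated correlation). Of the dendritic cell maturation genes, 12 of 27 genes rose, 1 fell and 14 were not past the test (14 and 2 adjusted over the list alone). Fscn1 stood at +3.61 ± 0.49 and Ccr7 at +1.64 ± 0.32 (list adjusted p = 2.58e-06, and 0.056 with an estimated correlation). Of the early stress genes tied to dissociation, 0 of 26 genes rose, 14 fell and 12 were not past the test (0 and 14 adjusted over the list alone). Nr4a1 stood at -1.94 ± 0.46 (list adjusted p = 6.73e-08, and 0.056 with an estimated correlation). Il23a (+0.17 ± 0.27), Cd274 (+0.80 ± 0.39) and Il1b (+0.78 ± 0.48) were not past the test, although without day 11 replicate 1 Il1b reached 1.73 (adjusted p = 0.00257). Krt24 (-4.90 ± 0.18), Skint9 (-4.74 ± 0.23) and the desmosomal protein Dsp (-4.03 ± 0.36) fell, and of the keratinocyte markers 3 of 25 genes rose, 11 fell and 11 were not past the test (4 and 12 adjusted over the list alone), list adjusted p = 3.18e-06, and 0.262 with an estimated correlation. The comparison called 2762 genes, 1452 higher and 1310 lower, and 1456 of them changed at least 2-fold.

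**Figure D3:**
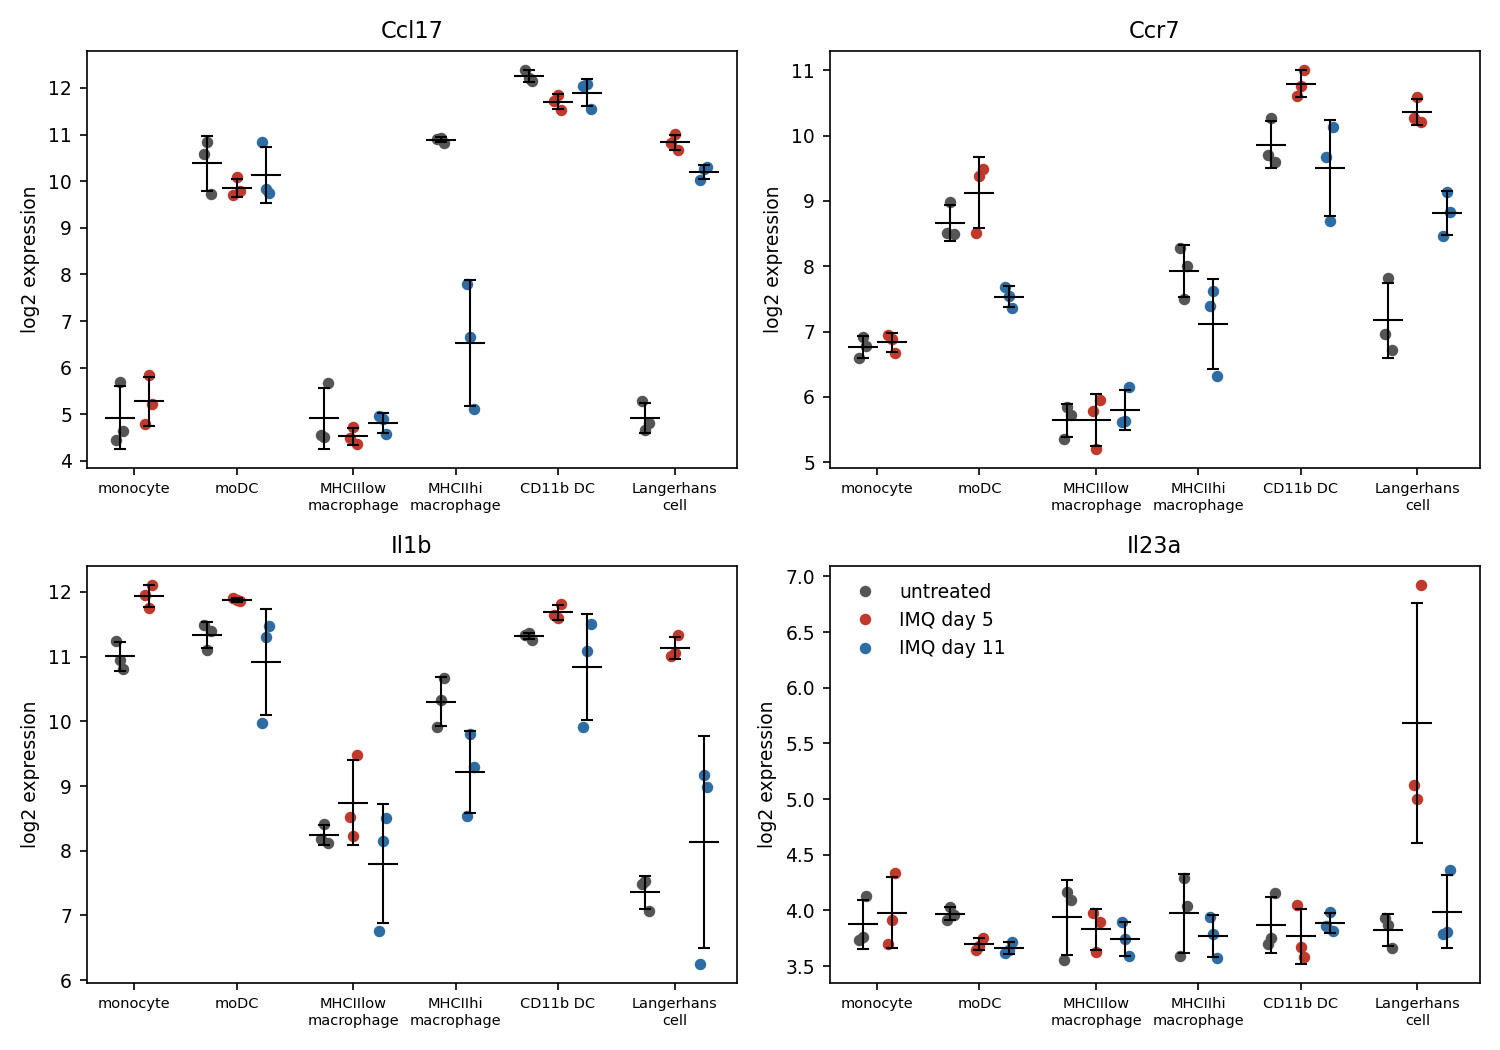
Log2 expression of Ccl17, Ccr7, Il1b and Il23a on each array (points) in the 16 groups. In Langerhans cells Il23a rose at day 5 by 1.86 ± 0.27 and at day 11 stood 0.17 ± 0.27 from untreated, whereas Ccl17 stood 5.28 ± 0.40 above it.

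The direct comparison of day 11 with day 5 in Langerhans cells, whose title letter also changes between these days, asks what differed later in the treatment. Ifitm1 (-4.01 ± 0.49), the mannose receptor Mrc1 (-3.36 ± 0.30), Plac8 (-3.25 ± 0.61), Ccr7 (-1.54 ± 0.32), the chemokine Cxcl10 (-2.42 ± 0.50) and Cd274 (-2.08 ± 0.39) fell. Il1b (-2.99 ± 0.48), Il23a (-1.70 ± 0.27) and Mki67 (-1.89 ± 0.30) fell too. Fitted with only these groups, they missed the threshold (adjusted p = 0.0998, 0.152 and 0.0516 in that order). Of the monocyte signature, 0 of 19 genes rose, 9 fell and 10 were not past the test (1 and 14 adjusted over the list alone), list adjusted p = 2.68e-14, and 0.000416 with an estimated correlation. Of the chemokines, 0 of 24 genes rose, 7 fell and 17 were not past the test (0 and 9 adjusted over the list alone). Ccl7 stood at -2.87 ± 0.43 (list adjusted p = 1.83e-11, and 0.00484 with an estimated correlation). In the regulatory list, 0 of 23 genes rose, 3 fell and 20 were not past the test (0 and 7 adjusted over the list alone), list adjusted p = 1.83e-06, and 0.00333 with an estimated correlation. Of the maturation genes, 0 of 27 genes rose, 4 fell and 23 were not past the test (0 and 13 adjusted over the list alone), list adjusted p = 3.66e-10, and 0.00484 with an estimated correlation. Of the G2 and M phase genes, 0 of 35 genes rose, 3 fell and 32 were not past the test (0 and 9 adjusted over the list alone), list adjusted p = 2.59e-11, and 0.0427 with an estimated correlation. Ccl17 (-0.63 ± 0.40), Ccl22 (-0.37 ± 0.45) and Top2a (-0.92 ± 0.30) were not past the test, and the receptor Gpr34 rose (+1.84 ± 0.34). The count was 330 genes, 90 higher and 240 lower. It was 1127 with array weights, 194 with only these groups fitted, and 191 without day 5 replicate 2, 172 without day 5 replicate 3 and 190 without day 11 replicate 3.

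MHCIIlow dermal macrophages at day 5 gained the B cell attractant Cxcl13 (+5.99 ± 0.27), the acute phase protein Saa3 (+5.87 ± 0.63) and S100a9 (+5.28 ± 0.43), and lost Rnase2a, a secreted ribonuclease (-3.73 ± 0.41), Retnla (-3.90 ± 0.78) and the lectin Siglech (-3.17 ± 0.37). Their cell division genes rose as well: of the G2 and M phase list, 33 of 35 genes rose, 0 fell and 2 were not past the test (33 and 0 adjusted over the list alone). Bub1 stood at +2.91 ± 0.28 and Birc5 at +2.81 ± 0.34 (list adjusted p = 4.26e-35, and 0.000848 with an estimated correlation). Of the S phase genes, 16 of 30 genes rose, 0 fell and 14 were not past the test (21 and 0 adjusted over the list alone). The thymidine kinase Tk1 stood at +2.28 ± 0.49 (list adjusted p = 7.41e-11, and 0.00577 with an estimated correlation), while Mki67 stood at +0.33 ± 0.30, not past the test. Of the oxidative phosphorylation genes, 21 of 30 genes rose, 0 fell and 9 were not past the test (23 and 0 adjusted over the list alone). Cycs stood at +1.56 ± 0.26 (list adjusted p = 1.76e-16, and 0.0175 with an estimated correlation). Of the NF-kB pathway genes, 1 of 21 genes rose, 11 fell and 9 were not past the test (1 and 15 adjusted over the list alone). The adhesion molecule Icam1 stood at -1.70 ± 0.26 and Cd83 at -1.82 ± 0.26 (list adjusted p = 1.48e-09, and 0.0397 with an estimated correlation). Early stress genes tied to dissociation fell as well: 0 of 26 genes rose, 11 fell and 15 were not past the test (0 and 14 adjusted over the list alone), list adjusted p = 1.76e-07, and 0.0465 with an estimated correlation. The macrophage growth factor receptor Csf1r fell (-0.96 ± 0.16). Mast cell markers were lower beside these groups: 0 of 8 genes rose, 4 fell and 4 were not past the test (0 and 6 adjusted over the list alone), list adjusted p = 0.00163, and 0.249 with an estimated correlation, and keratinocyte markers had a median of -0.14 (adjusted p = 0.228, and 0.801 with an estimated correlation). The test called 2208 genes, 1125 higher and 1083 lower, and 972 of them changed at least 2-fold.

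At day 11 MHCIIlow macrophages carried high Cxcl13 (+6.55 ± 0.27) against untreated cells, and the cytokines Il1a (-4.33 ± 0.53), Il6 (-3.29 ± 0.66) and Tnf (-2.77 ± 0.46) fell. Of the NF-kB genes, 1 of 21 genes rose, 10 fell and 10 were not past the test (1 and 13 adjusted over the list alone). Rel stood at -1.65 ± 0.35 (list adjusted p = 6.16e-12, and 0.042 with an estimated correlation). Of the inflammatory mediators, 2 of 22 genes rose, 7 fell and 13 were not past the test (2 and 8 adjusted over the list alone), list adjusted p = 0.000155, and 0.0938 with an estimated correlation. In the dissociation and early stress list, 0 of 26 genes rose, 9 fell and 17 were not past the test (2 and 14 adjusted over the list alone), list adjusted p = 1.51e-06, and 0.0938 with an estimated correlation. Of the G2 and M phase genes, 4 of 35 genes rose, 2 fell and 29 were not past the test (7 and 2 adjusted over the list alone), list adjusted p = 0.00205, and 0.373 with an estimated correlation. Fibroblast markers had a median of -0.85 (adjusted p = 0.0101, and 0.555 with an estimated correlation) and mast cell markers of -0.62 (adjusted p = 0.00766, and 0.361 with an estimated correlation). Neutrophil markers had a median of 0.10 (adjusted p = 0.112, and 0.309 with an estimated correlation) and B cell markers of 0.20 (adjusted p = 0.186, and 0.41 with an estimated correlation). Against day 5, the cell cycle genes had dropped: 0 of 35 genes rose, 20 fell and 15 were not past the test (0 and 31 adjusted over the list alone). Bub1 stood at -2.48 ± 0.28 (list adjusted p = 1.87e-82, and 2.49e-07 with an estimated correlation). Antigen presentation genes rose over the same interval: 4 of 19 genes rose, 0 fell and 15 were not past the test (6 and 0 adjusted over the list alone). H2-Eb1 stood at +1.71 ± 0.15 and the costimulatory receptor Cd28 at +2.02 ± 0.32 (list adjusted p = 2.78e-10, and 0.000262 with an estimated correlation). Keratinocyte markers had a median of 0.30 in that interval (adjusted p = 0.00115, and 0.37 with an estimated correlation). Day 11 against untreated gave 1516 genes, 675 higher and 841 lower (707 at least 2-fold, and 972 genes without day 11 replicate 2). Day 11 against day 5 gave 75 genes, 13 higher and 62 lower, which became 314 with array weights and 40, 46 and 43 without day 5 replicates 2, 3 and 4, and 37 and 43 without day 11 replicates 1 and 3.

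MHCIIhi macrophages at day 11 also gained Cxcl13 (+5.06 ± 0.27) and S100a8 (+6.26 ± 0.77), and lost Rnase2a (-5.04 ± 0.41), Il1a (-4.58 ± 0.53), Ccl17 (-4.36 ± 0.40) and the lectin Cd209b (-3.72 ± 0.33). A larger share of the NF-kB pathway genes fell than of any other list in this comparison: 0 of 21 genes rose, 17 fell and 4 were not past the test (0 and 20 adjusted over the list alone). Icam1 stood at -2.64 ± 0.26 and the signalling adaptor Traf1 at -1.90 ± 0.41 (list adjusted p = 4.61e-17, and 0.0301 with an estimated correlation). Of the early stress genes tied to dissociation, 1 of 26 genes rose, 11 fell and 14 were not past the test (2 and 11 adjusted over the list alone), list adjusted p = 6.54e-05, and 0.187 with an estimated correlation. Of the alternative activation genes, 1 of 26 genes rose, 13 fell and 12 were not past the test (1 and 14 adjusted over the list alone). Retnla stood at -4.10 ± 0.78 and Lyve1 at -2.84 ± 0.44 (list adjusted p = 1.48e-07, and 0.056 with an estimated correlation). Of the chemokines, 1 of 24 genes rose, 10 fell and 13 were not past the test (1 and 10 adjusted over the list alone). Ccl4 stood at -2.12 ± 0.43 (list adjusted p = 0.000286, and 0.187 with an estimated correlation). Keratinocyte markers were higher in the same samples, with the cornified envelope gene Sprr1b at +4.13 ± 0.59 and Krt16 at +3.22 ± 0.61: 13 of 25 genes rose, 0 fell and 12 were not past the test (14 and 0 adjusted over the list alone), median 1.21 (adjusted p = 5.5e-08, and 0.187 with an estimated correlation). The test called 2330 genes, 1162 higher and 1168 lower, and 1071 of them changed at least 2-fold. Median-centring moved the higher share from 49.9% to 59.99%. Fitting only these groups gave 1188, leaving out untreated replicate 4 gave 1374 and leaving out day 11 replicate 2 gave 1525.

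In moDC at day 5, S100a9 (+5.86 ± 0.43), Stfa3, another cysteine protease inhibitor (+5.27 ± 0.55) and Saa3 (+4.51 ± 0.63) rose, and Retnla (-4.50 ± 0.78), Krt15 (-3.95 ± 0.56) and Clca3a2 (-3.17 ± 0.35) fell. Mki67 fell (-2.01 ± 0.30); of the G2 and M phase genes, 0 of 35 genes rose, 4 fell and 31 were not past the test (0 and 5 adjusted over the list alone), list adjusted p = 0.0165, and 0.527 with an estimated correlation. Of the oxidative phosphorylation genes, 15 of 30 genes rose, 0 fell and 15 were not past the test (16 and 0 adjusted over the list alone). Ndufb8 stood at +1.13 ± 0.21 (list adjusted p = 7.04e-12, and 0.0397 with an estimated correlation). Of the glycolysis genes, 4 of 21 genes rose, 0 fell and 17 were not past the test (4 and 0 adjusted over the list alone). Tpi1 stood at +1.09 ± 0.20 (list adjusted p = 0.00234, and 0.0213 with an estimated correlation). Of the neutrophil markers, 6 of 14 genes rose, 0 fell and 8 were not past the test (7 and 0 adjusted over the list alone), S100a8 and S100a9 among them (adjusted p = 4.06e-06, and 0.00197 with an estimated correlation). Fibroblast markers moved with the falls, such as Col1a2 (-2.01 ± 0.43): 0 of 14 genes rose, 4 fell and 10 were not past the test (0 and 9 adjusted over the list alone), list adjusted p = 2.39e-05, and 0.3 with an estimated correlation. The count was 1761 genes, 886 higher and 875 lower (50.3% higher, 60.7% with quantile normalisation and 65.8% with median-centring), 711 of them at least 2-fold. It was 786 with only these groups fitted, and 1014 without untreated replicate 4, 978 without day 5 replicate 2 and 977 without day 5 replicate 3.

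At day 11, moDC had lower Il1a (-3.52 ± 0.53), the chemokine Ccl7 (-3.26 ± 0.43), Mki67 (-2.38 ± 0.30) and Il10 (-2.46 ± 0.47) than untreated moDC, and higher Cd72, a B cell and myeloid coreceptor (+3.43 ± 0.41). Of the NF-kB genes, 0 of 21 genes rose, 12 fell and 9 were not past the test (0 and 16 adjusted over the list alone). Icam1 stood at -2.33 ± 0.26 (list adjusted p = 6.27e-14, and 0.0301 with an estimated correlation). Early stress genes tied to dissociation were lower in the same samples: 1 of 26 genes rose, 7 fell and 18 were not past the test (3 and 10 adjusted over the list alone), list adjusted p = 0.00499, and 0.343 with an estimated correlation. Of the fibroblast markers, 0 of 14 genes rose, 7 fell and 7 were not past the test (0 and 10 adjusted over the list alone). Col1a2 stood at -2.18 ± 0.43 (list adjusted p = 1.51e-06, and 0.262 with an estimated correlation). Against day 5, glycolysis genes were lower: 0 of 21 genes rose, 2 fell and 19 were not past the test (0 and 5 adjusted over the list alone), list adjusted p = 0.000193, and 0.00484 with an estimated correlation, and Trem1, an amplifier of myeloid inflammation, fell (-2.88 ± 0.50). Day 11 against untreated gave 1313 genes, 403 higher and 910 lower (588 at least 2-fold; 30.7% higher, and 40.9% with quantile normalisation), 234 with only these groups fitted and 864 without day 11 replicate 1. Day 11 against day 5 gave 158 genes, 23 higher and 135 lower (100 at least 2-fold), but limma called 0 with only these groups fitted (1762 at an unadjusted p under 0.05), 303 with array weights, 264 with median-centred arrays, 98, 75 and 58 without day 5 replicates 2, 3 and 4, and 102 and 105 without day 11 replicates 2 and 3.

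CD11b DC at day 5 gained Ifitm1 (+5.13 ± 0.49), Cd72 (+4.62 ± 0.41) and the protease inhibitor Spint1 (+3.89 ± 0.34), and lost the growth factor receptor Flt1 (-3.21 ± 0.26) and the epoxide hydrolase Ephx1 (-3.15 ± 0.44). Some genes of the Langerhans cell identity list rose in these dermal cells: 6 of 22 genes rose, 0 fell and 16 were not past the test (8 and 0 adjusted over the list alone). Epcam stood at +2.62 ± 0.20, the adhesion molecule Cdh1 at +2.71 ± 0.36 and Mfge8 at +3.26 ± 0.49 (list adjusted p = 7.78e-06, and 0.0116 with an estimated correlation), while Cd207 stood at +0.99 ± 0.47, not past the test. Of the interferon-stimulated genes, 8 of 34 genes rose, 1 fell and 25 were not past the test (12 and 1 adjusted over the list alone). Irf7 stood at +2.62 ± 0.46 (list adjusted p = 1.49e-08, and 0.0397 with an estimated correlation). Of the neutrophil markers, 5 of 14 genes rose, 0 fell and 9 were not past the test (6 and 0 adjusted over the list alone). S100a9 stood at +3.76 ± 0.43 (list adjusted p = 2.48e-07, and 0.000848 with an estimated correlation). Of the NF-kB genes, 0 of 21 genes rose, 8 fell and 13 were not past the test (0 and 8 adjusted over the list alone), list adjusted p = 7.92e-06, and 0.131 with an estimated correlation, beside a dissociation list median of -0.16 (adjusted p = 0.0875, and 0.601 with an estimated correlation). T cell markers had a median of 0.47: 2 of 14 genes rose, 0 fell and 12 were not past the test (5 and 1 adjusted over the list alone), list adjusted p = 0.0201, and 0.259 with an estimated correlation. The count was 1244 genes, 470 higher and 774 lower (37.8% higher, and 27.5% with median-centring), 572 of them at least 2-fold. It was 1911 with array weights, 720 with only these groups fitted, and 827 without untreated replicate 4, 706 without day 5 replicate 2 and 775 without day 5 replicate 3.

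In CD11b DC at day 11, Epcam was still raised (+2.94 ± 0.20), and the lipoxygenase Alox15 (-3.77 ± 0.21), Il1a (-3.39 ± 0.53) and Flt1 (-2.94 ± 0.26) had fallen. Of the NF-kB genes, 0 of 21 genes rose, 12 fell and 9 were not past the test (0 and 17 adjusted over the list alone). Bcl3 stood at -2.12 ± 0.32 (list adjusted p = 4.74e-13, and 0.0315 with an estimated correlation). In the dissociation list, 1 of 26 genes rose, 7 fell and 18 were not past the test (1 and 8 adjusted over the list alone), list adjusted p = 0.00107, and 0.271 with an estimated correlation. Of the Langerhans cell identity genes, 6 of 22 genes rose, 1 fell and 15 were not past the test (6 and 1 adjusted over the list alone), list adjusted p = 0.000621, and 0.056 with an estimated correlation. Between day 5 and day 11 the chromatin organiser Satb1 (-2.98 ± 0.31) and the costimulatory ligand Tnfsf4 (-2.92 ± 0.33) fell, and of the maturation genes 0 of 27 genes rose, 5 fell and 22 were not past the test (0 and 11 adjusted over the list alone), list adjusted p = 3.27e-08, and 0.0131 with an estimated correlation. Keratinocyte markers had a median of 0.52 over that interval: 1 of 25 genes rose, 0 fell and 24 were not past the test (6 and 0 adjusted over the list alone), list adjusted p = 2.22e-05, and 0.247 with an estimated correlation. Day 11 against untreated gave 1612 genes, 553 higher and 1059 lower (731 at least 2-fold; 34.3% higher, and 22.04% with median-centring), 168 with only these groups fitted, 1008 without untreated replicate 4, 727 without day 11 replicate 2 and 767 without both arrays that stood apart. Day 11 against day 5 gave 150 genes, 40 higher and 110 lower, and 6 with only these groups fitted, 72 and 53 without day 5 replicates 3 and 4, 44 and 335 without day 11 replicates 2 and 3, and 50 without both arrays that stood apart.

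Dermal monocytes, profiled at day 5 only, gained Saa3 (+5.48 ± 0.63), Stfa3 (+4.98 ± 0.55) and Lcn2, an iron-binding acute phase protein (+4.16 ± 0.49), and Clca3a2 fell (-2.52 ± 0.35). Of the neutrophil markers, 6 of 14 genes rose, 0 fell and 8 were not past the test (6 and 0 adjusted over the list alone). S100a9 stood at +4.78 ± 0.43 (list adjusted p = 5.25e-06, and 0.00197 with an estimated correlation). Of the antigen presentation genes, 8 of 19 genes rose, 1 fell and 10 were not past the test (9 and 1 adjusted over the list alone). Psmb9 stood at +1.84 ± 0.19 (list adjusted p = 0.000105, and 0.0213 with an estimated correlation). Of the oxidative phosphorylation genes, 16 of 30 genes rose, 0 fell and 14 were not past the test (17 and 0 adjusted over the list alone). Ndufv2 stood at +1.11 ± 0.17 (list adjusted p = 2.78e-11, and 0.0459 with an estimated correlation). Fibroblast markers had a median of -0.75: 0 of 14 genes rose, 3 fell and 11 were not past the test (0 and 3 adjusted over the list alone), list adjusted p = 0.00511, and 0.538 with an estimated correlation. The count was 1986 genes, 1002 higher and 984 lower (50.5% higher, 64.1% with quantile normalisation and 66.8% with median-centring), 796 of them at least 2-fold. It was 277 with only these groups fitted, 1282 with array weights and 1196 without day 5 replicate 3.

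**Figure D4:**
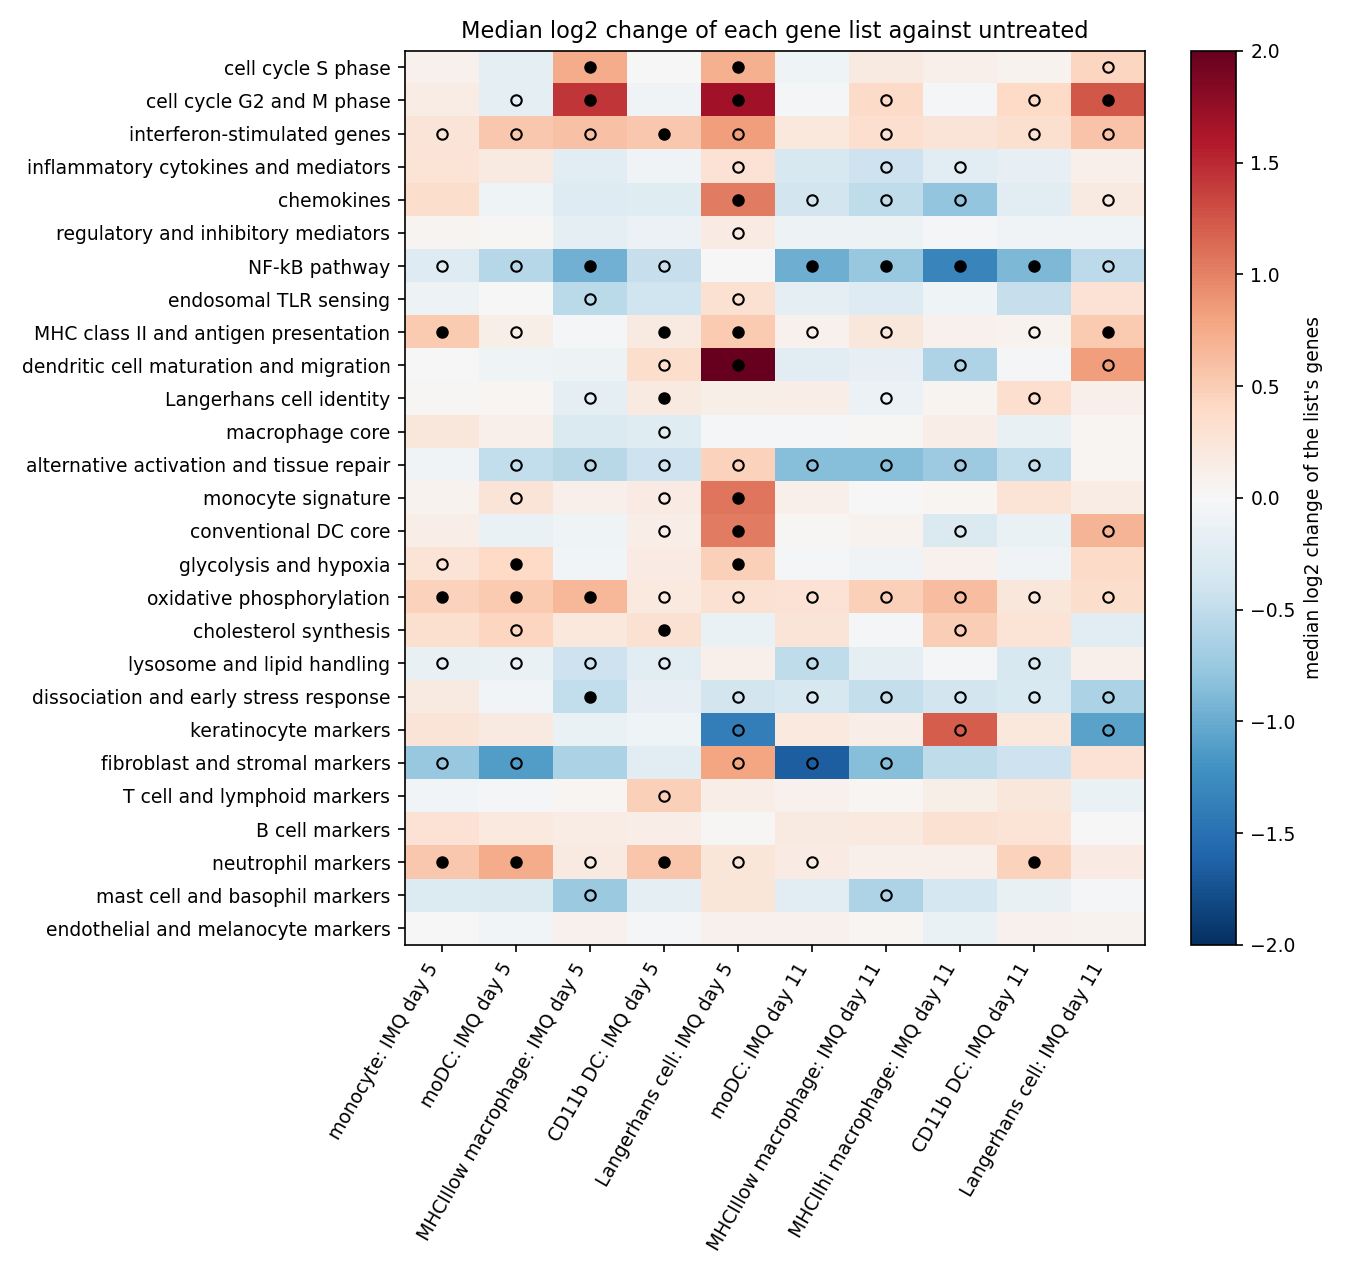
Median log2 change of each gene list (rows) in the 10 comparisons of imiquimod with untreated cells (columns), with colour limited to changes between -2 and 2. Filled circles mark lists with an adjusted p under 0.05 with an estimated correlation and open circles those past it only at the preset correlation, and the G2 and M phase list has medians of 1.68 in Langerhans cells and 1.43 in MHCIIlow macrophages at day 5.

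All 5 populations profiled at day 5 shared 71 genes past the test in the same direction, 40 higher and 31 lower, against 0.0107 and 0.0143 if the calls were independent. S100a8 (smallest change 3.97), S100a9 (3.76), the immunoproteasome genes Psmb8 (0.79) and Psmb9 (1.17), the Fc receptors Fcgr1 (1.01) and Fcgr4 (1.65) and the antiviral gene Oas1a (1.16) were among the shared rises. The shared falls at day 5 included genes of keratinocytes, Krt15 (smallest change 2.90), Dsc3 (1.36), Dsp (1.13) and Col17a1 (0.82), in dermal cells too. At day 11 all 5 then profiled shared 163 genes, 30 higher and 133 lower, against 0.0043 and 0.021. Calls share 1 variance per gene and are not independent, so the expected numbers decide nothing. A batch that followed the title letters would be shared at day 11 too. The shared falls at day 11 included Icam1 and Rel of the NF-kB pathway, the inflammasome gene Nlrp3, and the immediate early genes Nr4a2, Fosb and Gadd45b. The dissociation and early stress list, with Nr4a2, Fosb and Gadd45b among its genes, was lower at day 11 in all 5 populations at the preset correlation and in 0 of them with an estimated one (camera, adjusted p from 0.056 to 0.343). Which samples were digested at which temperature is not given, so dissociation was not tested. Of the shared genes, 18 genes at day 5 and 59 at day 11 changed at least 2-fold in every population, and array weights gave 113 at day 5.

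The response of Langerhans cells was then compared with the mean response of the 4 dermal populations, which asks what imiquimod changed differently in the epidermal cells. At day 5 the dermal populations were monocytes, moDC, MHCIIlow macrophages and CD11b DC. Their first title letter changes with treatment and that of Langerhans cells does not, so a batch that followed it would appear in this difference. Among its genes, Ccl17 (+6.19 ± 0.44), Retnla (+6.56 ± 0.87), Lilr4b, an inhibitory receptor (+5.61 ± 0.29), Ccr2 (+4.38 ± 0.42), Il1b (+3.18 ± 0.54), Mki67 (+2.75 ± 0.33) and Il23a (+1.96 ± 0.31) were higher in the response of Langerhans cells. Of the G2 and M phase genes, 29 of 35 genes were higher, 0 were lower and 6 were not past the test (33 and 0 adjusted over the list alone) in this difference (adjusted p = 1.72e-21, and 0.00402 with an estimated correlation). Of the maturation genes, 19 of 27 genes were higher, 0 were lower and 8 were not past the test (20 and 1 adjusted over the list alone). Fscn1 stood at +4.77 ± 0.55 (list adjusted p = 4.75e-14, and 0.00262 with an estimated correlation). Of the chemokines, 11 of 24 genes were higher, 2 were lower and 11 were not past the test (11 and 3 adjusted over the list alone), list adjusted p = 1.55e-07, and 0.0265 with an estimated correlation. Of the endosomal Toll-like receptor genes, 7 of 17 genes were higher, 0 were lower and 10 were not past the test (7 and 0 adjusted over the list alone). Unc93b1 stood at +3.10 ± 0.41 (list adjusted p = 5.23e-05, and 0.0265 with an estimated correlation). Of the conventional DC core, 21 of 35 genes were higher, 2 were lower and 12 were not past the test (24 and 3 adjusted over the list alone), list adjusted p = 1.96e-11, and 0.00262 with an estimated correlation. Krt24 (-5.23 ± 0.20) and Skint9 (-4.82 ± 0.25) were lower in this difference, and of the keratinocyte markers, 1 of 25 genes was higher, 11 were lower and 13 were not past the test (3 and 13 adjusted over the list alone), list adjusted p = 3.51e-05, and 0.248 with an estimated correlation. The difference was called for 2109 genes, 1141 higher and 968 lower, and 1221 of them reached 2-fold. The balance turned with quantile normalisation (985 higher and 1117 lower) and with no filter (1124 and 1150).

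At day 11 the dermal mean held MHCIIhi macrophages in place of monocytes, so the difference is not the same one as at day 5. It was largest for Ccl17 (+6.54 ± 0.44) and Rbp4 (+5.77 ± 0.30), and Ccl22 (+4.68 ± 0.51), Ccr7 (+2.18 ± 0.35) and Csf1r (+1.04 ± 0.18) were also higher. Among the cell cycle genes of G2 and M phase, 24 of 35 genes were higher, 0 were lower and 11 were not past the test (31 and 1 adjusted over the list alone). Aurkb stood at +2.11 ± 0.38 (list adjusted p = 8.94e-15, and 0.0156 with an estimated correlation). Of the maturation genes, 13 of 27 genes were higher, 1 was lower and 13 were not past the test (15 and 1 adjusted over the list alone), list adjusted p = 5.27e-10, and 0.00657 with an estimated correlation. Of the conventional DC core, 17 of 35 genes were higher, 2 were lower and 16 were not past the test (18 and 2 adjusted over the list alone), list adjusted p = 2.57e-07, and 0.0156 with an estimated correlation. Il23a (+0.34 ± 0.31), Cd274 (+0.85 ± 0.44) and Il1b (+1.39 ± 0.54) were not past the test, though without Langerhans cell day 11 replicate 1 Il1b reached 2.33 (adjusted p = 0.000371), and array weights gave 1.67 (0.0203). Without that replicate Mki67, called here at +1.29 ± 0.33, stood at 0.90 (adjusted p = 0.0834). In the full fit Mki67 changed by -0.21 in Langerhans cells and by -1.495 in the dermal mean. Keratinocyte markers were lower: 0 of 25 genes were higher, 13 were lower and 12 were not past the test (0 and 14 adjusted over the list alone). Dsp stood at -3.15 ± 0.40 (list adjusted p = 3.27e-12, and 0.0649 with an estimated correlation). The difference was called for 1932 genes, 1064 higher and 868 lower, and 1167 of them reached 2-fold.

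Lists of dissociation genes and of markers of other cell types were also called at the preset correlation in comparisons described above. Brackets give the median, then the adjusted p at the preset and at an estimated correlation. Fibroblast markers were higher in the response difference at day 5 (1.55, 2.07e-05 and 0.248) and at day 11 (1.13, 0.00081 and 0.36). They were lower in Langerhans cells at day 11 against day 5 (-0.35, 0.0305 and 0.6). Neutrophil markers were higher in CD11b DC (0.47, 0.00035 and 0.0301) and moDC (0.17, 0.00363 and 0.056) at day 11. They were higher in MHCIIlow macrophages at day 5 (0.18, 0.0105 and 0.0632). The same markers were lower in moDC at day 11 against day 5 (-0.07, 0.0348 and 0.155). Untreated, they were lower in moDC than monocytes (-0.12, 0.0229 and 0.0896) and in CD11b DC than moDC (-0.12, 0.00846 and 0.053). Keratinocyte markers were lower in untreated CD11b DC than in moDC (-0.85, 1.41e-06 and 0.166). They were higher in moDC at day 11 against day 5 (0.21, 0.0039 and 0.444). Mast cell markers were higher in the day 5 difference (0.80, 0.0296 and 0.382). Dissociation genes were lower at day 11 against day 5 in moDC (-0.27, 0.0157 and 0.354) and CD11b DC (-0.16, 0.0133 and 0.348). They were also lower in that interval in Langerhans cells (-0.11, 0.000555 and 0.213), and in the day 11 difference (-0.18, 0.031 and 0.382). They were higher in untreated moDC than in monocytes (0.14, 0.00894 and 0.312) and in Langerhans cells than in CD11b DC (0.28, 0.0392 and 0.435).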

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

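All tests of other populations' RNA, title letters, keratinocyte RNA and splits given here were chosen after the results were seen. Results stand here because the Langerhans cell response differed from the dermal mean in a direct test, or unused probe sets held a signal.

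At day 5 the difference was called for 2109 genes and at day 11, where the dermal mean holds MHCIIhi macrophages in place of monocytes, for 1932. A batch that followed the first title letter would also enter it, since that letter changes by day 5 in the dermal populations and not in Langerhans cells. At day 5 its log2 values were 6.56 for Retnla, 6.19 for Ccl17, 5.61 for Lilr4b, 4.38 for Ccr2, 4.33 for Ccl22, 3.18 for Il1b, 2.82 for Ccr7, 2.75 for Mki67, 2.52 for Top2a, 2.10 for Cd274, 1.96 for Il23a, 1.53 for Il10 and 0.66 for Csf1r. Lower in the difference at day 5 were Krt24 (-5.23), Skint9 (-4.82), Slurp2 (-4.59) and Il34 (-2.74). Il10 lost its call under several alternatives, quantile normalisation among them.

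The lists called at day 5, also with an estimated correlation, had median differences of 1.48 for G2 and M phase, 1.83 for dendritic cell maturation, 1.18 for the conventional DC core, 1.07 for chemokines and 0.64 for endosomal Toll-like receptor sensing. At day 11 these were 1.22 for G2 and M phase, 1.05 for dendritic cell maturation and 0.76 for the conventional DC core.

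At day 11 the gene values were 6.54 for Ccl17, 5.77 for Rbp4, 4.70 for Retnla, 4.68 for Ccl22, 3.002 for Ccr2, 2.62 for Il6, 2.18 for Ccr7, 2.12 for Top2a, 1.29 for Mki67 and 1.04 for Csf1r. Il6 changed by 0.08 in Langerhans cells and by -2.54 in the dermal mean. It lost its call when some single Langerhans cell arrays were left out. Krt24 (-4.87), Skint9 (-4.86), Acer1 (-4.29) and Il34 (-2.93) were lower.

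Of 100 random splits, 1, the real one, gave as many genes as the day 5 difference. The highest other split gave 1942, and it kept or mirrored the Langerhans cell labels. For day 11, 2 of 100 splits gave as many genes, the highest other giving 2129, again with the Langerhans cell labels kept or mirrored. Splits that mixed those labels gave at most 6 genes at day 5 and 75 at day 11. The counts thus follow the Langerhans cell labels, so chance is not excluded for a difference from the dermal response.

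G2 and M phase genes were higher in Langerhans cells at both days, as in MHCIIlow macrophages at day 5, whose RNA could be a source. To give the list's level, the smallest share of another population's RNA would be 121% at day 5 (MHCIIlow macrophages, whose own marker genes allow a median of 7.57%) and 93.2% at day 11 (CD11b DC, 10.2%), which argues against that source at both days. At day 5 the marker genes of CD11b DC allow a median of 26.1% (5.92% to 73.9%), where the list would need 262%. RNA of other populations was weighed for this list only. It stays open for the maturation, chemokine, monocyte and conventional DC genes. At day 5 the median change is 1.68 within the same first title letter, which argues against a difference between first letters. Letter pairs differ, so a batch stays open, as at day 11, where 0 letters hold both groups. For keratinocyte RNA, list sums include each population's baseline and cannot decide (moDC held 76.6% of needed signal at day 5, 103% at day 11). In MHCIIhi macrophages at day 11 (71.3%) keratinocyte markers changed by a median of 1.21 and the list by -0.03. Keratinocyte profiles may differ by population, so RNA of dividing keratinocytes stays open beside division of Langerhans cells.

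Keratinocyte markers changed in Langerhans cell samples at day 5, where the abundant Krt5 went from 12.24 to 10.94 (10.51 to 9.59 in moDC), although the gate asks for CD11b, MHC class II and CD24. A lower share of unchanged keratinocyte RNA would lower them all, and 4 rose while 13 fell past the test, which argues against it as the whole cause. RNA of keratinocytes that themselves changed, carried in every sorted population, may be a source. Across the 25 markers, the changes in Langerhans cells correlated with those in the dermal populations at a median r of 0.705 (0.653 to 0.715), against 0.208 to 0.311 across all genes, and genes are not independent replicates. Langerhans cells may also change these genes themselves, which was not tested.

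Changes common to the 4 dermal populations at day 5 follow the title letters as well as the treatment. Of these genes 86.0% had the same sign in Langerhans cells, whose untreated and day 5 arrays share a first letter. With a median change of 0.39 in that direction, this argues against that letter as the whole cause for the genes. Of 49 probe sets with no gene symbol that changed alike, 31 (63.3%) shared the sign in Langerhans cells (median 0.10), so letters stay open there. Parts due to batch and to a response common to all the cells stay open.

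Probe sets with no symbol or several symbols, 9298 tested with limma, held 368 past the test in Langerhans cells at day 5 and 412 at day 11.

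For the comparisons of 3 arrays with 3, 10 splits are too few for a share under 0.05, and in each the real split alone, 1 of 10, gave as many genes. The real and highest other counts at day 5 were 1986 and 67 in monocytes, 1761 and 3 in moDC, 2208 and 2 in MHCIIlow macrophages, 1244 and 3 in CD11b DC, and 2514 and 6 in Langerhans cells. At day 11 they were 1313 and 44 in moDC, 1516 and 3 in MHCIIlow macrophages, 2330 and 12 in MHCIIhi macrophages, 1612 and 5 in CD11b DC, and 2762 and 71 in Langerhans cells. For day 11 against day 5 they were 158 and 3, 75 and 2, 150 and 3, and 330 and 35 in moDC, MHCIIlow macrophages, CD11b DC and Langerhans cells. Between untreated populations they were 534 and 481 for moDC against monocytes, 140 and 35 for the macrophages, 557 and 18 for CD11b DC against moDC, and 3603 and 3 for Langerhans cells against CD11b DC. The shared genes, 71 at day 5 and 163 at day 11, were reached by 1 of 100 splits, the real one, with a highest other of 0 (limma). Mixed labels leave few called genes in any population, so an overlap of 0 there does not bear on the sharing.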

How the results depend on the processing

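Only leaving out both arrays that stood apart was chosen after the data were seen. Across all settings run, none of the named genes or lists reversed direction while called. Of 1317 named gene results, the call was lost in 253 and gained in 10 when only the groups compared were fitted, in 60 and 8 with array weights, 38 and 7 without both arrays that stood apart, 36 and 3 with median-centring, 33 and 2 with quantile normalisation, 28 and 15 with the replicate block, 27 and 0 with no filter, 10 and 0 with the mean of probe sets, and 4 and 0 with trend and robust options. The stricter filter lost 1 and gained 2 of 1313, and leaving out single arrays lost 814 and gained 22 of 11742. With only the groups compared, day 5 gene counts fell to 277 in monocytes but rose to 2875 in Langerhans cells. No cause was tested, and the number of arrays limits all fits.

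Same-numbered replicates had a median r of 0.009 over 29 pairs of 1 population (3 over 0.1) and 0.044 over 100 pairs of 1 treatment (78 above 0, 19 over 0.1, 1 under -0.1, highest 0.327). The latter lean to positive values, but most pairs lie under 0.1, so the numbers were not taken to pair the samples. As a block they moved moDC at day 11 against day 5 to 254 and Langerhans cells against CD11b DC to 2030. Quantile normalisation and median-centring moved the share of called genes that were higher at day 5 from 50.5% to 64.1% and 66.8% in monocytes and from 50.3% to 60.7% and 65.8% in moDC. Quantile normalisation also moved it from 30.7% to 40.9% in moDC at day 11, and in the day 5 response difference from 54.1% to 46.9% (49.4% with no filter). Where higher and lower calls were near even, their balance turned with at least 1 setting: monocytes, moDC, MHCIIlow macrophages and Langerhans cells at day 5, MHCIIhi macrophages and Langerhans cells at day 11, CD11b DC against moDC, and Langerhans cells against CD11b DC. It also turned for the untreated macrophages when MHCIIhi replicate 1 was left out (101 and 103). Median-centring moved it from 37.8% to 27.5% and from 34.3% to 22.04% in CD11b DC at days 5 and 11, from 49.9% to 59.99% in MHCIIhi macrophages, from 53.9% to 66.8% for CD11b DC against moDC, and from 48.6% to 38.5% for Langerhans cells against CD11b DC. Median-centring moved the median of all genes from -0.01 to -0.12 in moDC at day 11 against day 5.

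The 2-fold threshold asks for a larger change by construction. It gave 796, 711, 972, 572 and 1349 at day 5 (monocytes, moDC, MHCIIlow macrophages, CD11b DC, Langerhans cells), 588, 707, 1071, 731 and 1456 at day 11 (moDC, MHCIIlow, MHCIIhi, CD11b DC, Langerhans cells), 100 and 212 for day 11 against day 5 in moDC and Langerhans cells, 351 for moDC against monocytes, 1995 for Langerhans cells against CD11b DC, 1221 and 1167 for the response differences, and 18 and 59 shared genes. Fitting only the groups compared gave 277, 786 and 720 at day 5 in monocytes, moDC and CD11b DC, 234, 1188 and 168 at day 11 in moDC, MHCIIhi macrophages and CD11b DC, 0 (limma, 1762 unadjusted), 6 and 194 for day 11 against day 5 in moDC, CD11b DC and Langerhans cells, and 76, 19 and 191 for untreated moDC against monocytes, the macrophages, and CD11b DC against moDC. Array weights gave 1282 and 1911 at day 5 in monocytes and CD11b DC, 303, 314 and 1127 for day 11 against day 5 in moDC, MHCIIlow macrophages and Langerhans cells, 258 for moDC against monocytes and 113 shared genes at day 5. Median-centring gave 264 for moDC at day 11 against day 5. Without both arrays that stood apart, CD11b DC gave 767 at day 11 and 50 against day 5, and moDC against monocytes 825.

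Leaving out each array in turn gave 1196 to 1917 genes in monocytes, 977 to 1661 in moDC, 1535 to 1777 in MHCIIlow macrophages, 706 to 1032 in CD11b DC and 1942 to 2206 in Langerhans cells at day 5. At day 11 it gave 864 to 1166 in moDC, 972 to 1200 in MHCIIlow, 1374 to 2178 in MHCIIhi, 727 to 1882 in CD11b DC and 2084 to 2582 in Langerhans cells. Day 11 against day 5 gave 58 to 179, 37 to 55, 44 to 335 and 172 to 364 in moDC, MHCIIlow, CD11b DC and Langerhans cells. Untreated pairs gave 410 to 735, 104 to 204, 357 to 524 and 2981 to 3220 in the order of the report, and the differences 1567 to 2207 and 1545 to 2005.

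With an estimated in place of a preset correlation, the number of contrasts that called a list went from 8 to 4 for S phase, 15 to 9 for G2 and M phase, 16 to 2 for interferon-stimulated genes, 11 to 0 for inflammatory mediators, 14 to 5 for chemokines, 7 to 3 for regulatory mediators (4 with quantile normalisation, array weights or the block), 17 to 5 for NF-kB, 9 to 2 for endosomal Toll-like receptors, 13 to 7 for MHC class II, 12 to 6 for maturation, 5 to 2 for Langerhans cell identity, 6 to 1 for macrophage core, 15 to 3 for alternative activation, 10 to 5 for the monocyte signature, 15 to 3 for oxidative phosphorylation, 10 to 2 for cholesterol synthesis, 10 to 2 for lysosome, 13 to 1 for dissociation, 11 to 1 for keratinocytes, 9 to 1 for fibroblasts, 2 to 0 for T cells, 10 to 4 for neutrophils and 4 to 1 for mast cells. The conventional DC core was called in 12 contrasts and glycolysis in 6, neither moved over 1.5 times. B cells, and endothelial cells with melanocytes, were called in 0 (camera), and the block gave 1 for the latter.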

Other observations

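Metabolic genes moved in several populations beyond those described above. In MHCIIhi macrophages at day 11, of the oxidative phosphorylation genes 15 of 30 measured genes rose, 0 fell and 15 were not past the test (19 and 0 adjusted over the list alone). Ndufb8 stood at +1.23 ± 0.21 and Cycs at +1.16 ± 0.26 (list adjusted p = 4.74e-13, and 0.056 with an estimated correlation). In CD11b DC at day 5, of the cholesterol synthesis genes 3 of 20 measured genes rose, 0 fell and 17 were not past the test (3 and 0 adjusted over the list alone). The mevalonate pathway enzymes Pmvk stood at +2.13 ± 0.26 and Fdps at +1.38 ± 0.24 (list adjusted p = 0.000303, and 0.0465 with an estimated correlation). Glycolysis genes in Langerhans cells at day 5 included the lactate transporter Slc16a3 (+1.39 ± 0.33) and Pgk1 (+1.16 ± 0.17): 9 of 21 genes rose, 1 fell and 11 were not past the test (9 and 1 adjusted over the list alone), list adjusted p = 0.00504, and 0.0322 with an estimated correlation. Among the endosomal Toll-like receptor genes of Langerhans cells at day 5, 6 of 17 genes rose, 0 fell and 11 were not past the test (6 and 0 adjusted over the list alone). Unc93b1 stood at +2.89 ± 0.37 and Tlr13 at +2.46 ± 0.44 (list adjusted p = 0.00139, and 0.0694 with an estimated correlation), while Tlr7, the receptor for imiquimod, stood at +0.14 ± 0.39, with both means below the filter threshold and not past the test.

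In CD11b DC at day 5 the haem oxygenase Hmox1 (-2.80 ± 0.31) and the scavenger receptor Cd163 (-2.39 ± 0.35) fell: of the macrophage core genes, 2 of 45 genes rose, 10 fell and 33 were not past the test (2 and 13 adjusted over the list alone), list adjusted p = 0.00203, and 0.322 with an estimated correlation. The same list was not called in moDC at day 5, with a median of 0.10 (adjusted p = 0.23, and 0.763 with an estimated correlation), nor in MHCIIlow macrophages, with -0.30 (adjusted p = 0.139, and 0.694 with an estimated correlation). Single genes fell there. In moDC at day 5 the lipid scavenger receptor Cd36 (-2.59 ± 0.50) and the growth factor Igf1 (-2.23 ± 0.40) fell, and in MHCIIlow macrophages the lectin Cd209a (-2.91 ± 0.33) and the receptor kinase Axl (-1.78 ± 0.38). Ccl20, a chemokine of inflamed epidermis, fell in the Langerhans cell samples at day 11 (-3.24 ± 0.42).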
